A study of Mus musculus with 6 samples.

How the data were processed

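RNA sequencing of mouse corneal epithelial sheets was analysed from 1 table of counts per gene for 6 samples. Per the labels, 3 samples are wild type and 3 are EphA2 null, and per the series design text total RNA was extracted with a miRNeasy kit and sequenced on an Illumina HiSeq. The deposited values are raw counts, whole numbers per gene identified by Ensembl gene number, with different totals per sample. The aligner, the counting program, the strand setting, the genome build and the annotation used by the authors are not given in the sources used here. Counts were assigned to samples by column name, and 0 columns of other samples were present.

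The table held 25006 genes, of which 6617 had 0 counts in all samples. Gene names and positions were taken from GENCODE M21 on GRCm38, which had 24991 of the 25006 identifiers; this annotation was not checked against the one used for counting. The 13 genes of the mitochondrial chromosome had 0 counts in every sample, so their list could not be tested. Without a stated strand setting, reads of a gene and its antisense partner or overlapping gene cannot be told apart, and genes with near-identical copies, such as ribosomal protein genes, are uncertain. The 20 most abundant genes took between 17.2% and 17.6% of the counts of each library. Total counts ran from 15308013 to 27586942 per library. No pair of samples had counts within sampling noise of each other (chi-square per degree of freedom of at least 11.2), so all 6 were counted separately.

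Counts were normalised with TMM factors, genes were filtered with filterByExpr, which left 12847, and genotypes were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with genotype as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of its F value, and log2 fold changes are the libraries labelled EphA2 null over wild type. DESeq2 1.42.0 and limma voom (limma 3.58.1) were run as alternatives. For genes with few counts the ratio of summed counts, adjusted for effective library size, is given with an exact 95% interval, which covers counting error only.

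The test, the samples, the named genes, 34 gene lists and most alternatives were fixed before the data were examined. The lists cover autophagy, cilium and lysosome, signalling pathways, epithelial identity, stress responses and markers of other cell types. Lists with at least 5 tested genes, 24 in all, were tested with camera on log2 CPM (prior count 3, inter-gene correlation 0.01, two-sided), adjusted over the 24 lists; an estimated correlation and fry were alternatives, and neither kept a call. 5 genes stand in more than 1 list. Named genes are Epha2, then the 12 largest rises and 12 largest falls among called genes with a mean of at least 1 CPM and no overlap between the groups. If fewer than 5 genes passed, the 10 genes with the smallest p were to be named as not passing, which applied here. For each list up to 4 called members, or otherwise up to 2 members with the smallest p, were to be named. For most lists fewer members, or none, are named below. Genes within 10 Mb of Epha2 were compared with all others by Fisher's exact test, with 5 and 20 Mb as alternatives. Genes named outside these rules were chosen after their values were seen.

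The range of the number in the sample titles, with 3 samples in a lower and 3 in a higher range, was taken up after the data were seen, because the libraries separated by it. It was added as a term to the edgeR, DESeq2, voom, camera and fry models, and the log2 fold change within each range is given beside pooled values. Other alternatives were other normalisation factors, other filters, other thresholds, each sample left out in turn, and the sum of samples that share a title number.

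The edgeR step was tested on simulated counts drawn from the means and library sizes of the real samples, with 50 genes changed at each size. For genotype alone (12735 genes) it recovered 2% of genes changed 1.5-fold, 30% at 2-fold and 98% at 4-fold and at 8-fold, with 14 false calls. For genotype with the title number range as a term (12714 genes) it recovered 50%, 86%, 98% and 100%, with 15 false calls. The changed genes had a mean of at least 1 CPM. For genotype alone the simulated means did not hold the separation of the libraries by title number. Changes of about 2-fold or less could therefore be missed with genotype alone, and the limit in the real data can lie higher. There, edgeR with genotype alone did not call Padi2 at 20.6-fold (adjusted p = 0.980) or Npy at 5.14-fold (adjusted p = 0.370). Exon-level counts and sequence variants were not analysed here.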

Results

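Total RNA from corneal epithelial sheets, the layered cell sheet that covers the front of the eye, was sequenced from wild type mice and from mice labelled EphA2 null. EphA2 is a receptor tyrosine kinase that binds ephrin-A ligands on neighbouring cells, and the title of the series places the comparison in a study of cilium formation and autophagy in this tissue. There were 3 wild type libraries and 3 libraries labelled EphA2 null. Total counts were 20138496, 16302476 and 15308013 in wild type 1, 2 and 3, and 20897761, 21661491 and 27586942 in the libraries labelled EphA2 null 1, 2 and 3. The basal keratin gene Krt5 and the corneal keratin gene Krt12 had mean levels of 26975 and 14588 CPM (read counts scaled to a common library size, TMM-normalised) over the 6 libraries. The sample titles carry a number that is shared by wild type 1 and 2 and by the libraries labelled EphA2 null 2 and 3. A letter after the number differs between samples that share it. The numbers fall in a lower range (wild type 1 and 2 and the library labelled EphA2 null 1) and a higher range (wild type 3 and the libraries labelled EphA2 null 2 and 3). The labels do not say that the samples are separate animals, so the p-values measure the spread between these samples, which may be technical.

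Epha2 itself (ENSMUSG00000006445, chromosome 4, 141301240 to 141329384 in GRCm38) was not lower in the libraries labelled EphA2 null. Its level was 298, 253 and 563 CPM in wild type 1, 2 and 3, and 285, 653 and 578 CPM in the libraries labelled EphA2 null 1, 2 and 3. The log2 fold change, libraries labelled EphA2 null over wild type, was 0.44 ± 0.39 (SE, n = 3 per group), with an adjusted p of 0.9996 in edgeR's quasi-likelihood test. The levels followed the title numbers: Epha2 was higher by 1.07 on the log2 scale in the 3 libraries with the higher numbers than in the 3 with the lower numbers (adjusted p = 0.00174, edgeR). Between the genotypes, the log2 fold change was 0.05 within the lower and 0.13 within the higher title numbers. The counts are per gene and would not show the loss of a single exon. Because the Epha2 level does not show the labelled genotype, every direction given here rests on the label alone. The 3 libraries are called the libraries labelled EphA2 null throughout.

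The clearest difference between the genotypes was in Padi1, which encodes a peptidylarginine deiminase, an enzyme that converts arginine in proteins to citrulline. Padi1 (ENSMUSG00000025329, chromosome 4, 140812983 to 140845778 in GRCm38, 0.455 Mb from Epha2) rose from 2.08 ± 0.420 CPM in the wild type libraries to 31.8 ± 4.45 CPM in the libraries labelled EphA2 null (SD, n = 3 each). The levels were 2.46, 1.63 and 2.16 CPM in wild type 1, 2 and 3, and 27.3, 32.0 and 36.2 CPM in the libraries labelled EphA2 null 1, 2 and 3. The log2 fold change was 3.92 ± 0.22 (SE), a 15.2-fold difference, with an adjusted p of 0.00339 in edgeR's quasi-likelihood test. It was 3.75 within the lower title numbers and 3.96 within the higher ones. With samples that share a title number summed, which leaves 2 samples per group, the log2 fold change was 3.85 and the adjusted p 0.202 in edgeR.

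**Figure D1:**
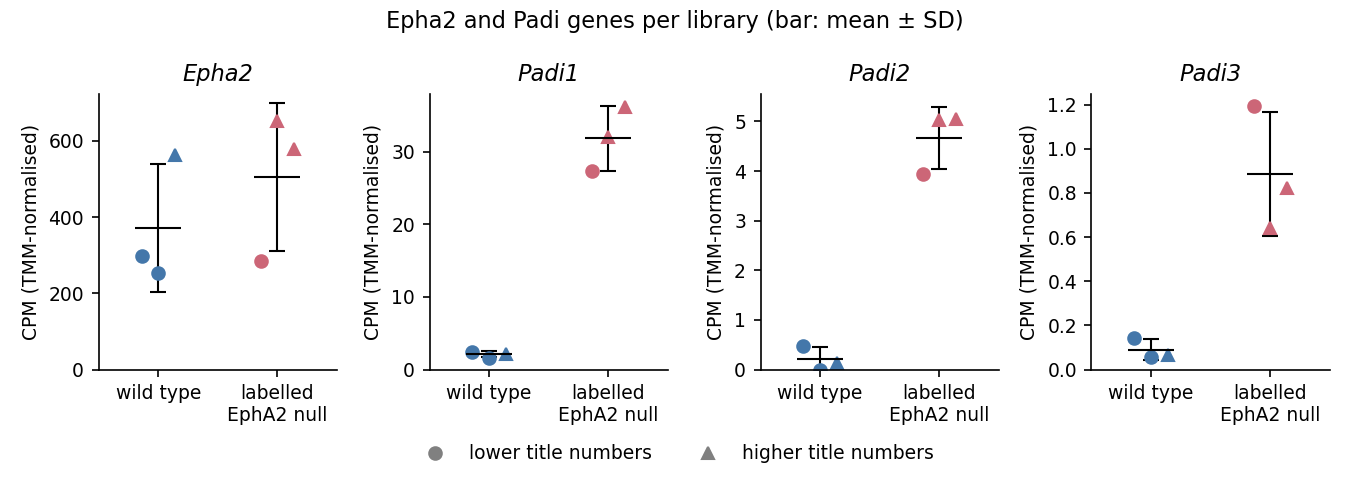
Levels in CPM (TMM-normalised) of Epha2, Padi1, Padi2 and Padi3 in each of the 3 wild type libraries (blue) and the 3 libraries labelled EphA2 null (red), with bars for the mean and SD and the marker shape for the title number range. Epha2 lies at 298 CPM or less in the libraries with lower title numbers of both genotypes, while Padi1 lies between 27.3 and 36.2 CPM in the libraries labelled EphA2 null and at 2.46 CPM or less in wild type.

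Padi1 was the only one of 12847 tested genes past an adjusted p of 0.05 in edgeR, with 0 genes lower. At an unadjusted p under 0.05 there were 152 genes, or 1.18%, which is below the share of 0.05 expected by chance. limma voom also called 1 gene, Padi1. DESeq2 called 4 genes higher and 1 lower, and 164, or 0.892%, at an unadjusted p under 0.05. The 4 higher were Padi1, Padi2, Npy, which encodes the neuropeptide Y precursor, and Samd11, and the lower one was the transcript 5830444B04Rik. With the title number range as a term in the model, edgeR called 1 gene, Padi1, and DESeq2 called 6 higher and 11 lower. Among the higher were Olfm4 (log2 fold change 0.97) and AA467197 (1.06), each with an adjusted p of 1.77e-08 in DESeq2. Among the lower were Fos (-0.62, adjusted p = 0.0269) and Junb (-0.45, adjusted p = 0.00201). Of the 5 genes called by DESeq2 without the term, Padi2 (adjusted p = 0.112) and Samd11 (adjusted p = 0.691) were not called with it, although their log2 fold changes were no smaller, 4.40 without and 4.54 with the term for Padi2 and 2.81 and 3.04 for Samd11.

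The genes with the next smallest p-values in edgeR did not pass the adjusted threshold and are given as values. Padi2 and Padi3 are the neighbours of Padi1 on chromosome 4 and encode enzymes of the same family. Padi2 had 323 counts in the libraries labelled EphA2 null and 12 in wild type, a depth-adjusted ratio of 20.6 (95% counting interval 11.6 to 40.3), with an adjusted p of 0.980 in edgeR, 2.84e-09 in DESeq2 and 0.112 in DESeq2 with the title number range as a term. Padi3 had 61 counts against 5, a ratio of 9.33 (95% counting interval 3.79 to 29.8; adjusted p = 0.980 in edgeR and 0.468 in DESeq2). These intervals cover counting error only. Npy was at 3.65 ± 0.498 CPM in the libraries labelled EphA2 null and 0.709 ± 0.150 CPM in wild type (SD, n = 3 each), a log2 fold change of 2.36 ± 0.29 (SE) with an adjusted p of 0.370 in edgeR and 1.25e-05 in DESeq2. The transcript 5830444B04Rik had 2 counts in the libraries labelled EphA2 null and 75 in wild type, a ratio of 0.0204 (95% counting interval 0.00243 to 0.0763). The others among the 10 smallest p-values had an adjusted p of 0.9996 in edgeR. Of these, Zbtb8b, a zinc finger gene, had a log2 fold change of -0.82 ± 0.16 (SE). For Scand1 it was -1.43 ± 0.32, for Pdzrn4 -2.06 ± 0.44, for Mobp, a myelin gene, -1.21 ± 0.27, and for the chemokine gene Cxcl14 1.32 ± 0.29. DESeq2 with the title number range as a term called Zbtb8b (adjusted p = 0.00166) and Scand1 (adjusted p = 0.0395), both lower. It did not call Pdzrn4, Mobp or Cxcl14. Without the term DESeq2 called neither Zbtb8b nor Scand1 (adjusted p = 0.105 for each). All 10 genes had no overlap between the groups, each library labelled EphA2 null lying on 1 side of each wild type library. Over all tested genes 3.73% were separated in this way, against 10% by chance for 3 exchangeable samples against 3, a value that takes no account of the separation of the libraries by title number.

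Called genes were also compared by distance from Epha2. Within 10 Mb of Epha2, 1 of 218 tested genes was called, Padi1, against 0 of 12629 elsewhere (Fisher's exact test, two-sided, p = 0.0170). With 1 call this p is only the share of tested genes that lie in the window. With an unadjusted p under 0.05 in edgeR, a criterion chosen after the data were seen, 8 of 218 genes lay near Epha2 and 144 of 12629 elsewhere, or 3.67% against 1.14% (Fisher's exact p = 0.00440). Without the Padi genes it was 5 of 214, or 2.34% (Fisher's exact p = 0.104), with 1 of 74 within 5 Mb (p = 0.579) and 10 of 388 within 20 Mb (p = 0.0150).

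**Figure D2:**
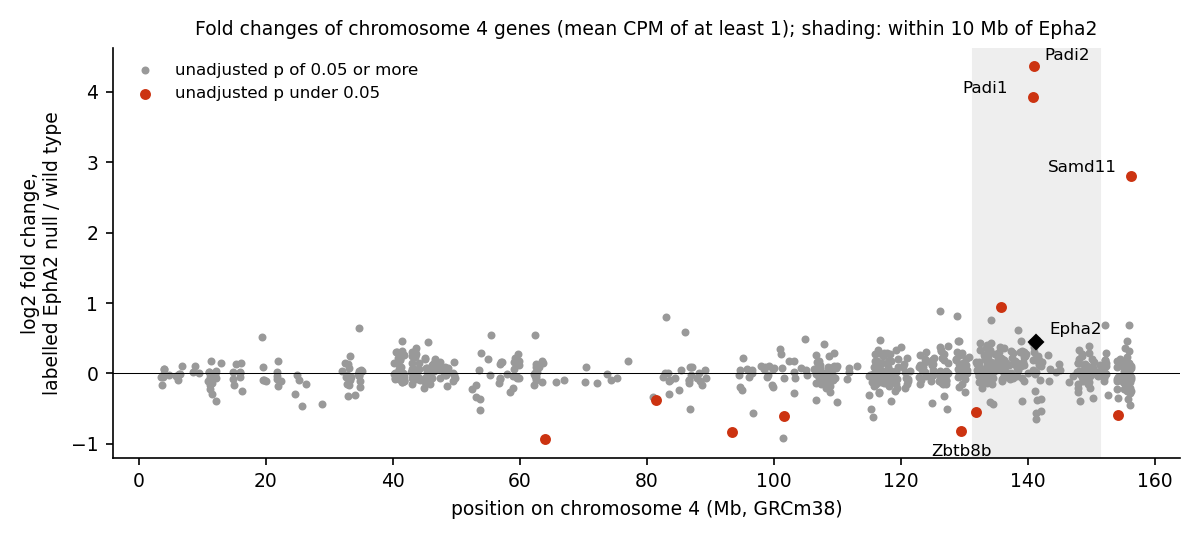
Log2 fold change (libraries labelled EphA2 null over wild type, n = 3 each) of chromosome 4 genes with a mean of at least 1 CPM, by position in Mb, with genes at an unadjusted p under 0.05 in red, Epha2 as a black diamond and the 10 Mb on each side of Epha2 shaded. Padi1 at 3.92 and Padi2 at 4.36 stand next to Epha2 at 0.44, and Samd11 at 2.80 lies beyond the shaded part.

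For autophagy, the machinery genes (from the Ulk1 initiation complex to the Atg8-family proteins) lay close to 0. Of 43 measured members, 0 were called in either direction over all genes and 0 had an unadjusted p under 0.05 in edgeR. The median log2 fold change was 0.03, with 26 members above 0 and 17 below, and no member further from 0 than 0.56 (camera adjusted p = 0.436). The smallest p-values belonged to Optn, an autophagy receptor, with a log2 fold change of 0.56 ± 0.27 (SE; adjusted p = 0.9996, edgeR), and Atg9a with 0.37 ± 0.31. The 40 lysosomal genes had a median of 0.06 and 0 called members (camera adjusted p = 0.223), and Lipa, the lysosomal acid lipase, had 0.27 ± 0.15.

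The 66 measured genes of the primary cilium (intraflagellar transport, BBSome and transition zone genes) had a median log2 fold change of -0.01, with 28 above 0 and 38 below (camera adjusted p = 0.778). None was called by edgeR or DESeq2, and 0 had an unadjusted p under 0.05 in edgeR. Kif17, a ciliary kinesin gene, had 1.24 ± 0.68 (SE) at 1.08 CPM or less on average in either group, and Tctn3, a transition zone gene, -0.30 ± 0.20. The 11 measured Hedgehog pathway genes had a median of -0.03 (camera adjusted p = 0.436) and the 17 Notch pathway genes one of 0.17 (camera adjusted p = 0.436), again with 0 called members.

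Of the 24 lists tested, camera called 2 in the libraries labelled EphA2 null against wild type. The 14 leukocyte markers were lower, with a median log2 fold change of -0.71 and 12 of the 14 below 0 (adjusted p = 0.00376; adjusted p = 0.975 with an estimated correlation). Csf1r, a macrophage receptor gene, had -1.24 ± 0.80 (SE) and the complement gene C1qa -1.16 ± 0.81, at mean levels of 1.03 and 1.02 CPM in wild type. These markers also differed between the title numbers, with a median of -2.06 in the higher against the lower ones. The genotype call was lost without wild type 1 (median -0.16, adjusted p = 0.144), without the library labelled EphA2 null 3 (median -0.12, adjusted p = 0.323), with genes limited to a mean of at least 1 CPM (median -0.35, adjusted p = 0.108) and with the title number range as a term (median -0.21, adjusted p = 0.0817). It held with a median of -2.00 without the library labelled EphA2 null 1 and of -0.41 without the library labelled EphA2 null 2. The 20 genes of the unfolded protein and integrated stress response were higher, with a median of 0.15 and 17 of the 20 above 0 (camera adjusted p = 0.0170; adjusted p = 0.975 with an estimated correlation). Ddit3, a stress transcription factor gene, had 0.44 ± 0.22 and Hspa5, an endoplasmic reticulum chaperone gene, 0.40 ± 0.22. That call was lost without wild type 3 (adjusted p = 0.0868) and without the library labelled EphA2 null 2 (median 0.08, adjusted p = 0.566). With the title number range as a term the median was 0.08 (adjusted p = 0.0221; adjusted p = 0.763 with an estimated correlation and 0.870 with fry). Without that term no member of either list was called over all genes or adjusted over the list alone.

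No other list was called by camera, and their medians, with few members, are given as values. The Eph receptors and ephrins other than Epha2 had a median of 0.09 (15 genes, adjusted p = 0.927), and the feedback and target genes of ERK signalling one of 0.08 (19 genes, adjusted p = 0.249). Genes of corneal epithelial identity had a median of 0.14 (19 genes, adjusted p = 0.206), basal and limbal epithelial genes 0.12 (19 genes, adjusted p = 0.316), desmosome genes 0.09 (16 genes, adjusted p = 0.913), and adherens and tight junction genes 0.08 (30 genes, adjusted p = 0.316). Cxcl14, in the basal and limbal list, was, without the title number term, the only member of any list to pass when adjusted over the list alone (adjusted p = 0.0467). Cell cycle genes had a median of -0.12 (33 genes, adjusted p = 0.105) and cornified envelope and stress keratin genes 0.10 (19 genes, adjusted p = 0.316), among which Krt16 had 1.69 ± 0.51 (SE). The interferon response had a median of 0.20 (32 genes, adjusted p = 0.0634), which depended on single libraries. It was 0.36 (adjusted p = 2.32e-09) without wild type 1 and 0.28 (adjusted p = 2.80e-05) without the library labelled EphA2 null 2, but -0.09 (adjusted p = 0.272) without wild type 3 and -0.11 (adjusted p = 0.187) without the library labelled EphA2 null 3. Inflammation and chemokine genes had a median of 0.04 (20 genes, adjusted p = 0.804), sterol biosynthesis 0.06 (21 genes, adjusted p = 0.316), and immediate early genes 0.18 (21 genes, adjusted p = 0.822). NRF2 targets had -0.01 (24 genes, adjusted p = 0.913), with a camera direction of higher, nuclear genes of oxidative phosphorylation -0.02 (40 genes, adjusted p = 0.778) and ribosomal protein genes -0.02 (39 genes, adjusted p = 0.105). Markers of stromal keratocytes and fibroblasts had 0.17 (7 genes, adjusted p = 0.468) and of conjunctival epithelium 0.08 (12 genes, adjusted p = 0.822). Fewer than 5 genes were measured in the lists for corneal endothelium, nerve and Schwann cell, vessel, melanocyte, skeletal muscle, lens, retina, erythrocyte and sex-linked genes, which were not tested, and 0 of their members were called.

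Several of these lists passed camera when 1 library was left out. Without the library labelled EphA2 null 1, which leaves only higher title numbers in that group, cell cycle (-0.24, adjusted p = 0.00521), ribosomal protein (-0.19, adjusted p = 0.00521) and oxidative phosphorylation genes (-0.17, adjusted p = 0.0462) were lower. Notch pathway (0.34, adjusted p = 0.00982), ERK (0.34, adjusted p = 0.00982), junction (0.25, adjusted p = 0.00982), sterol (0.19, adjusted p = 0.00843), corneal identity (0.21, adjusted p = 0.0495) and interferon genes (0.28, adjusted p = 0.0270) were higher. Without wild type 3, which leaves only lower title numbers in that group, cell cycle (-0.27, adjusted p = 0.00193), oxidative phosphorylation (-0.15, adjusted p = 0.0188) and ribosomal protein genes (-0.12, adjusted p = 0.0188) were lower and ERK genes (0.33, adjusted p = 0.0188) higher. Without the library labelled EphA2 null 3, cornified envelope and stress keratin (0.28, adjusted p = 1.22e-04), inflammation (0.24, adjusted p = 0.0181) and conjunctival genes (0.32, adjusted p = 8.55e-04) were higher and Hedgehog genes lower (-0.22, adjusted p = 0.0451). Conjunctival genes also passed without wild type 1 (0.28, adjusted p = 0.0287), interferon genes without wild type 2 (0.12, adjusted p = 0.0462) and, as lower, immediate early genes without the library labelled EphA2 null 2 (-0.18, adjusted p = 0.0112). Without that library the medians of cell cycle and cornified envelope genes changed sign, to 0.02 and -0.03, and did not pass.

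**Figure D3:**
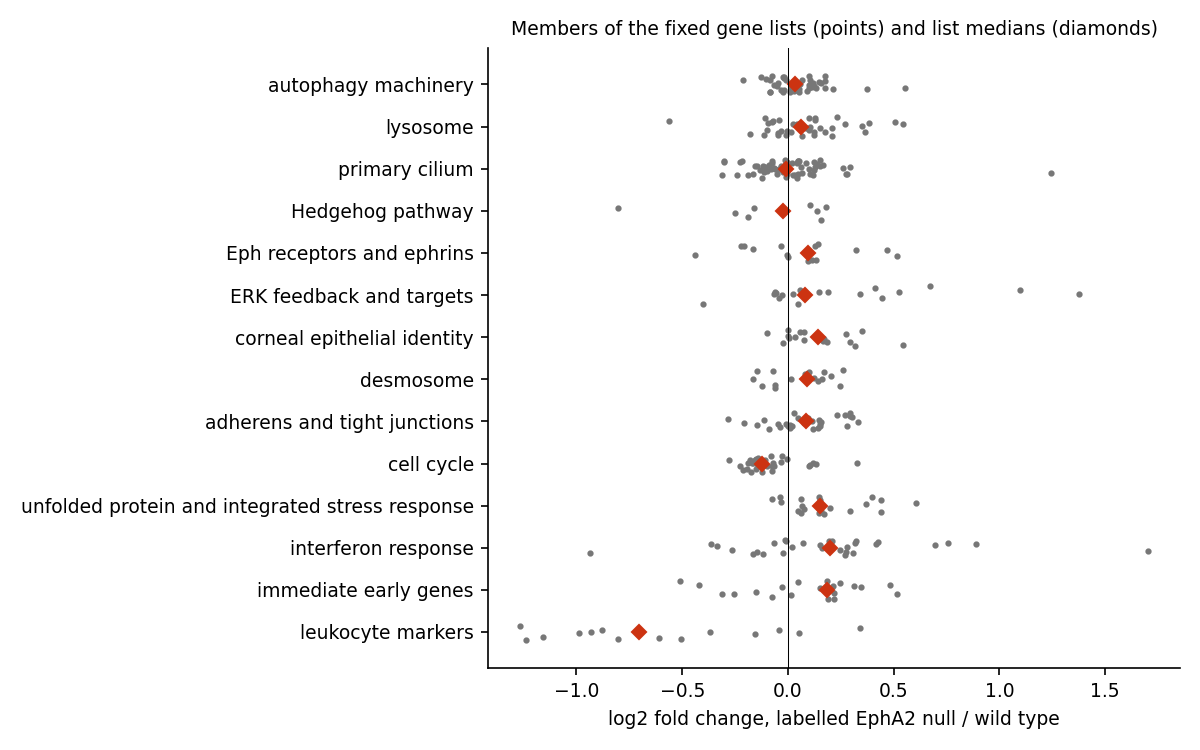
Log2 fold changes (libraries labelled EphA2 null over wild type, n = 3 each) of the measured members of 14 gene lists, 1 grey point per gene, with the list median as a red diamond. The medians of autophagy (0.03), lysosome (0.06) and primary cilium (-0.01) genes lie near 0, and leukocyte markers (-0.71) lie lowest.

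With the title number range as a term, a model added after the data were seen, camera called 7 of the 24 lists, each by a small median and none with an estimated correlation (adjusted p of at least 0.763). Eph receptors and ephrins were lower with a median of -0.15 (adjusted p = 0.00919; 0.763 with an estimated correlation), as were immediate early genes with -0.04 (adjusted p = 0.0221; 0.763). Oxidative phosphorylation had 0.09 (adjusted p = 0.00235; 0.763), NRF2 targets 0.06 (0.0230; 0.763), the interferon response 0.15 (0.0221; 0.828), the unfolded protein response 0.08 (0.0221; 0.763) and conjunctival markers 0.30 (0.0221; 0.763). In the immediate early list 5 genes were lower when adjusted over the list alone, with an adjusted p of 0.0160 in edgeR for each. They were Fos with a log2 fold change of -0.62, Junb with -0.45, Jund with -0.43, Egr1 with -0.40 and Ier2 with -0.36. Fos and Junb also passed over all genes in DESeq2 with the term. Chac1 in the unfolded protein response list was higher on this criterion, with 0.44 (adjusted p = 0.0439), and so was Cxcl14 in the basal and limbal list, with 1.12 (adjusted p = 0.0241).

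The libraries differed more by title number than by genotype. The first principal component held 62.0% of the variance and separated wild type 1, wild type 2 and the library labelled EphA2 null 1, with lower title numbers, from the other 3. Across genes, Pearson correlations of log2 CPM were 0.986 to 0.991 between libraries of 1 title number range and 0.963 to 0.977 across the ranges, whether or not the genotype was shared. edgeR called 3154 genes higher and 2586 lower in the higher title numbers than in the lower ones. The biological coefficient of variation was 0.236 with genotype alone and 0.127 with the title number range as a term. Each title range held both genotypes, 2 libraries of 1 and 1 of the other.

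**Figure D4:**
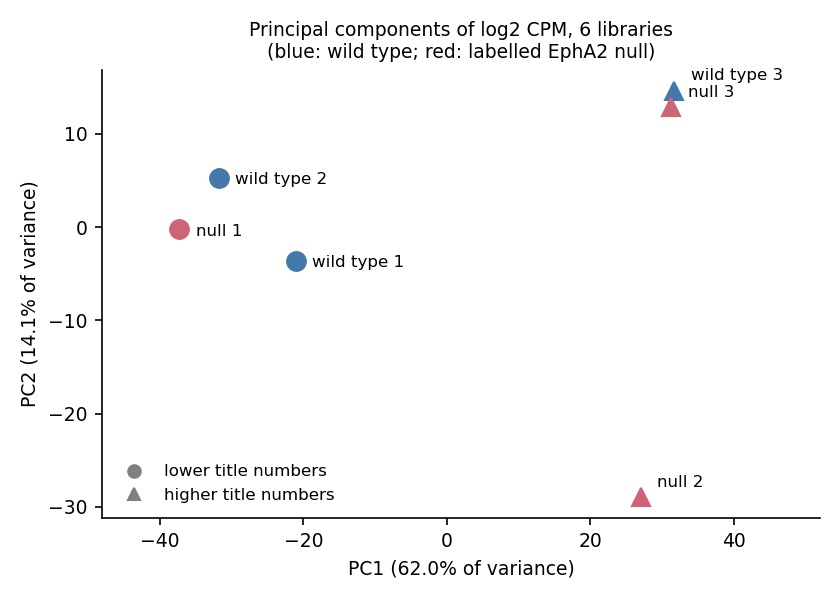
First and second principal components of log2 CPM for the 3 wild type libraries (blue) and the 3 libraries labelled EphA2 null (red), with circles for lower and triangles for higher title numbers. The first component, with 62.0% of the variance, separates the title numbers, and the library labelled EphA2 null 2 stands apart on the second, with 14.1%.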

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

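The alternatives with the title number range as a term were chosen after the data were seen. The 1 gene called by edgeR became 5 with DESeq2, 0 with samples of 1 title number summed (fewer samples) and 17 with DESeq2 and the title number range as a term; Padi1 was among the calls in every setting except the sum, where its log2 fold change was 3.85 (adjusted p = 0.202, against a highest value of 4.07 and a lowest of 3.78 over 18 alternatives). Leaving out any 1 sample left 1 call, Padi1. The 2 lists called by camera became 0 with an estimated correlation, 0 with fry, 4 with camera on ranks, 7 with the title number range as a term, 0 with that term and an estimated correlation and 0 with that term and fry. With 1 sample left out the number ran from 3 to 11. It was 5 without wild type 3, 11 without the library labelled EphA2 null 1 and 5 without the library labelled EphA2 null 3. With the title number range as a term, the medians of Eph receptors and ephrins (-0.15), immediate early genes (-0.0436) and oxidative phosphorylation (0.0942) had the opposite direction to the fit without it and passed; immediate early genes also did so without the library labelled EphA2 null 2 (-0.18, the lowest of the leave-one-out values, the highest being 0.35). The cause was not tested. Of the values of named genes 187 kept their direction and side of the threshold, 1 was weaker and 7 passed newly. Of 336 list values 291 kept their side of the threshold, 73 of them with the other direction and uncalled in both fits; 14 were weaker, 27 passed newly and 4 reversed. Epha2 stayed above 0 and uncalled in all 18 alternatives (0.08 to 0.86). Autophagy, lysosome and primary cilium were uncalled in all 14. The lists' calls depend on an assumed correlation of 0.01 between genes. Depth limits Padi2, Padi3 and 5830444B04Rik, with at most 12 counts in the lower group. Genes near Epha2 had a Fisher's exact p between 0.00277 and 0.0308 over 5 alternatives that include the Padi genes. With 2 choices changed together the Fisher's exact p ran from 4.17e-06 to 0.0449. It was 4.17e-06 and 3.60e-04 for DESeq2 calls within 20 and 5 Mb. For an unadjusted p under 0.05 it was 7.71e-04 and 0.0137 within 20 and 5 Mb, and 0.0449 and 8.13e-04 with the title number term. Without the Padi genes the Fisher's exact p at an unadjusted p under 0.05 was 0.104 (10 Mb), 0.579 (5 Mb) and 0.0150 (20 Mb).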

Other observations

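Each test in this part was chosen after the data were seen, apart from the split counts for the gene lists and the fixed lists. For the tests of Padi read sharing, the share of calls kept after the base composition correction, other cell types and the clock, what each outcome would mean was written down before the outcome was known. Between the higher and the lower title numbers camera called 12 lists, of which 0 passed with an estimated correlation (smallest adjusted p = 0.642). In the higher numbers, genes of Notch signalling (median log2 difference 0.60, camera adjusted p = 0.00248), ERK feedback and targets (0.52, 0.00138), Eph receptors and ephrins (0.75, 0.00106), adherens and tight junctions (0.45, 0.00138), immediate early genes (0.51, 0.00251) and sterol biosynthesis (0.22, 0.0319) were higher (adjusted p = 0.642 to 0.664 with an estimated correlation). Notch1 rose by 1.59, Egr1 by 1.54 and Klf4, a corneal epithelial transcription factor gene, by 1.46 on the log2 scale, each past the adjusted threshold in edgeR. H60c, a ligand gene for an activating receptor of lymphocytes, rose by 3.94. Cell cycle genes (-0.51, 1.03e-04), nuclear oxidative phosphorylation genes (-0.33, 7.61e-05), ribosomal protein genes (-0.34, 0.00191), NRF2 targets (-0.27, 0.0165), leukocyte markers (-2.06, 0.00138) and conjunctival markers (-0.62, 0.0165) were lower (adjusted p = 0.642 with an estimated correlation). Of the 14 leukocyte markers, 10 passed as lower and 1 as higher in edgeR, against 2586 and 3154 of 12847 over all tested genes. Of the 12 conjunctival markers, 4 passed as lower and 1 as higher.

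With the title number range as a term, genes at an unadjusted p under 0.05 between genotypes clustered in 4 of 255 windows of 10 Mb, all away from Epha2. On chromosome 14 from 10 to 20 Mb there were 10 of 19 genes, 5 higher and 5 lower in the libraries labelled EphA2 null, among them Thrb, a thyroid hormone receptor gene, and Ptprg (adjusted p = 1.16e-07, hypergeometric test). On chromosome 2 from 120 to 130 Mb there were 18 of 102 (adjusted p = 7.69e-06), among them Duox1 and its maturation factor Duoxa1, both lower, and on chromosome 12 from 70 to 80 Mb 12 of 59 (adjusted p = 1.75e-04). On chromosome 14 from 0 to 10 Mb there were 4 of 10 (adjusted p = 0.0245), against 3.86% of all tested genes with a position on a chromosome. Without the term 0 windows passed. A hypothesis is that some animals carry DNA segments of another strain there. Such segments need not follow the genotype, and another of the 9 splits that keep the title ranges, with the libraries labelled EphA2 null 1 and 2 set apart, also gave 4 windows (smallest adjusted p = 0.00534). A further split, with wild type 1 and the library labelled EphA2 null 3 set apart, gave 3 windows (smallest adjusted p = 5.09e-06). Sequence variants were not analysed here and neighbouring genes can be regulated together, so the hypothesis stays open.

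Epha2 counts in the libraries labelled EphA2 null were not reduced (log2 fold change 0.44). A disrupted allele may still give a transcript that is counted over the rest of the gene, and counts per gene, with their log2 fold change of 0.44, hold no value that decides this. For the same reason Epha2 does not check the labels. A single wrong label or a swap stays open, with the lowest level in the libraries labelled EphA2 null at 1.12 times the lowest wild type level, and so does an exchange of both labels as a whole, with the inverse ratio at 0.889. Padi1 separates the groups as labelled but was picked by that separation, so it does not test the labels.

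Padi1, Padi2 and Padi3 were all higher in the libraries labelled EphA2 null, and all 3 lie next to Epha2. A further Padi gene within 5 Mb of Epha2 was tested and did not have an unadjusted p under 0.05 in edgeR. Reads shared between the copies are argued against for Padi2, since 0% of the 31-base windows of its transcripts occur in Padi1 transcripts. For Padi3 the share was only 0.976%. Padi3 had 61 counts in the libraries labelled EphA2 null, and Padi1 had 595, 651 and 969 in libraries 1, 2 and 3. The share of windows takes no account of these levels, so it cannot exclude that some Padi3 counts came from Padi1. Skin or hair follicle cells, which express these genes, are argued against by Krt1, Krt10 and Tchh, the 3 of 13 detected skin and hair markers with enough counts to be tested, with a median log2 fold change of -0.0745 and no more than 6.29 CPM in any library. A difference around the Epha2 locus carried with the null allele cannot be told apart here from the loss of EphA2, which the design names: without the Padi genes, 5 of 214 genes within 10 Mb had an unadjusted p under 0.05 against 144 of 12629 elsewhere (Fisher's exact p = 0.104). The p was 0.579 within 5 Mb, with 1 of 74 genes, and 0.0150 within 20 Mb, so the locus stays open.

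The split by title number may come in part from base composition and transcript length: after a smooth correction for both in each library, 47.2% of the genes called between the title numbers were still called with the same sign. The correction as made did not account for the whole split, since 3609 genes were called after it, 2706 of them also before with the same sign. It cannot exclude such bias as the whole cause, because a smooth correction may leave part of the bias behind. Between genotypes, Padi1 kept a log2 fold change of 3.84 after the correction (adjusted p = 8.16e-04, edgeR), which does not bear on the title numbers. Animals of different sex are argued against by Ddx3y, a Y-linked gene, at 94.0 CPM or more in all 6 libraries. Light-phase clock genes such as Dbp were higher by a median of 0.88. Genes of the opposite phase were not lower (median 0.14), with Npas2 higher by 0.63. By what was written beforehand, this outcome speaks against the hour of collection. It cannot exclude it, since 6 of the 10 light-phase genes passed as higher and 0 as lower (3154 of 12847 higher over all tested genes). Only 5 genes of the opposite phase were measured, so the hour of collection stays open. For other cell types, the highest median, 0.46 for stromal markers, had the opposite sign to leukocyte and conjunctival markers. By what was written beforehand, this outcome speaks against a share of other cell types. It cannot exclude one, because only 2 of the 7 stromal genes passed as higher, while 10 of the 14 leukocyte markers passed as lower and 1 as higher. These counts of passing genes were not part of what was written. A share of other cell types therefore cannot be told apart from other differences. Library or collection batch and the state of the animals were not tested.

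The 3 against 3 design allows 10 splits, too few for a share under 0.05. The genotype split gave 1 gene, and 2 splits gave as many, the real one included. The highest other split gave 6088 genes and is the one that follows the title numbers (fitted as the only term, where the 3154 higher and 2586 lower genes come from a fit that also has the genotype), which points to a structure of the samples. For the gene lists the genotype split gave 2, the fewest of the 10 splits. Every other split gave more, from 5 to 13. Among the 9 splits that keep the title ranges, with the range as a term, the genotype split gave 1 gene and the highest other 4.

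Among the 10 genes with the smallest p between genotypes, 5 lie on chromosome 4, which holds 6.45% of the tested genes; 3 of the 5 are the adjacent Padi1, Padi2 and Padi3.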
